A study of Mus musculus with 20 samples.

How the data were processed

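Messenger RNA was sequenced from 20 hearts of C57BL/6J mouse fetuses at embryonic day 18.5. Per the labels' protocols, dams were put on their diet at 12 weeks of age, either a control diet with 10% of calories from fat or an obesogenic diet with 40% of calories from fat and free access to a 20% sucrose solution, and the dams on the obesogenic diet were mated after a weight gain of 25%. Sires ate the control diet, total RNA was isolated with a column kit and libraries were prepared with a stranded polyA kit, per the labels' protocols. The labels give 4 groups of 5 libraries each, control male, obese male, control female and obese female, where control and obese name the dam. Libraries are numbered 1 to 5 within their group.

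The authors deposited a table of estimated read counts for 40147 RefSeq transcripts with gene symbols and positions, per the file headers. The submitters' processing notes name CASAVA 1.8, STAR 2.5.3a, Partek and the mm10 build, with no role or order, and no source says how reads were split between transcripts. Of the deposited counts, 55.8% were whole within a tolerance of 0.001, so the table holds estimated counts rather than tallies of reads. A second deposited table gives 33228 of the transcripts as scaled signal. Within each library its values equalled the estimated counts multiplied by one factor, with 0.0001 added, and the deposited files do not say how the factors were chosen. The scaled signal entered only as an alternative. No mitochondrially encoded transcript is in either table.

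Transcript counts were summed by the gene symbol in the table, giving 24796 genes, and rounded. Near-identical gene copies, such as the paired globin genes, can share reads, and the split between their counts is uncertain. Such copies within a gene list are not separate readings. Positions are given on mm10 with both ends counted from 1. Ends in the table lay 1 base past those of the reference annotation of the same build for 65.0% of matched genes, so 1 was subtracted. Totals per library ran from 1.478 to 7.056 M estimated counts with a median of 4.228 M. CPM below use TMM-scaled totals for the group means of single genes, and for the plot of Cd36, Srebf2 and other single genes by group. The plain library totals were used for sums over marker genes. They were also used where the CPM of a single gene is given in the text for one library, as a range or as a median. Values of a gene on these different scales are not directly comparable.

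Genes were tested with edgeR 4.0.16 in R 4.3.3 after TMM normalization and filterByExpr with its minimum count of 10. One model held a mean for each of the 4 groups over all 20 libraries, with robust quasi-likelihood dispersions. Contrasts gave the effect of maternal obesity averaged over the sexes, within males and within females, the difference between the male and female effects, and the difference between sexes averaged over diets. P-values are two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. P-values measure only the spread between these samples, since the labels do not say whether fetuses come from separate dams. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the 52 lists with at least 3 genes left by the filter. Each list was tested again with a correlation estimated from the data and with fry. The lists, the markers of cell types and of other organs, the contrasts and every alternative not said to be added later were fixed before the data were examined.

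Named genes followed a rule fixed in the same way. For each diet contrast it takes up to 10 genes past the threshold in each direction and, where fewer than 5 pass, those with the smallest p up to 5, with a mean of at least 1 CPM. For the difference between the diet effects and for the sex contrast it takes the 6 genes with the smallest p in each direction. For each list described it takes the 3 members with the smallest p, and a fixed panel of cardiac and metabolic genes is read in the contrast averaged over the sexes. Genes named outside the rule are said to be so, and some genes that the rule picks are not reported here. The lists described were chosen among those called, after their values were seen.

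Alternatives were DESeq2 1.42.0, other size factors in edgeR, other filters on low counts, limma-voom, surrogate variables from svaseq in sva 3.50.0, the deposited scaled signal with pseudocounts of 1 and 0.1, single transcripts, models of one sex, and fits without each library in turn. A library was taken as rich in another organ's transcripts when its summed markers of lung, liver, or lymphocytes and thymus exceeded the median of all libraries by 20 times. Fits without such libraries, exact permutation tests of the mean log2 CPM of each list, and tests with all libraries thinned to the smallest total were added after the data were seen. Also added later were the values of the described lists in the alternative fits, and the counts of lists called within each sex in them. The permutation tests exchanged diet labels within each sex, without keeping libraries with the same number in their titles together. The 20 libraries carry 10 such numbers, 5 for each diet. Libraries with the same number correlated more than others in the median, as given further below, so these p can be too small.

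The edgeR step was tested on simulated counts with the real means, dispersions and library sizes and 200 changed genes among 12858 tested. In the contrast averaged over the sexes it recovered 12% of genes changed 1.25-fold, 54% of those changed 1.5-fold, 76% of those changed 2-fold and 92% of those changed 4-fold. In the male contrast it recovered 2%, 16%, 56% and 86%. Without the 3 libraries rich in lung transcripts, among 12728 simulated genes, the first 4 shares were 24%, 68%, 98% and 96%. Unchanged genes called numbered 4, 3 and 5 in these runs. The changed genes were drawn from the more abundant ones, and each gene varied on its own. Joint shifts of other organs' transcripts were thus not simulated, and the shares may not hold for the real libraries. Files were read and drawn with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.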

Results

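Hearts of 20 mouse fetuses near term were compared by polyA RNA sequencing, 10 from control dams and 10 from dams made obese by a diet rich in fat and sugar, with 5 male and 5 female fetuses in each diet group. Totals ran from 1.478 to 4.498 M estimated counts in control males, 2.914 to 4.191 M in control females, 3.626 to 5.859 M in obese males and 3.457 to 7.056 M in obese females. After the filter on low counts 12924 genes were tested.

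The transcripts of sex-linked genes separated male from female libraries as labelled in all 20 cases. Xist, the RNA that silences one X chromosome, lay between 383.3 and 648.5 CPM in the 10 female libraries and at most 1.59 CPM in the 10 male libraries. The Y-linked gene Eif2s3y lay between 51.1 and 74.3 CPM in male libraries and at most 0.239 CPM in female libraries.

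**Figure D1:**
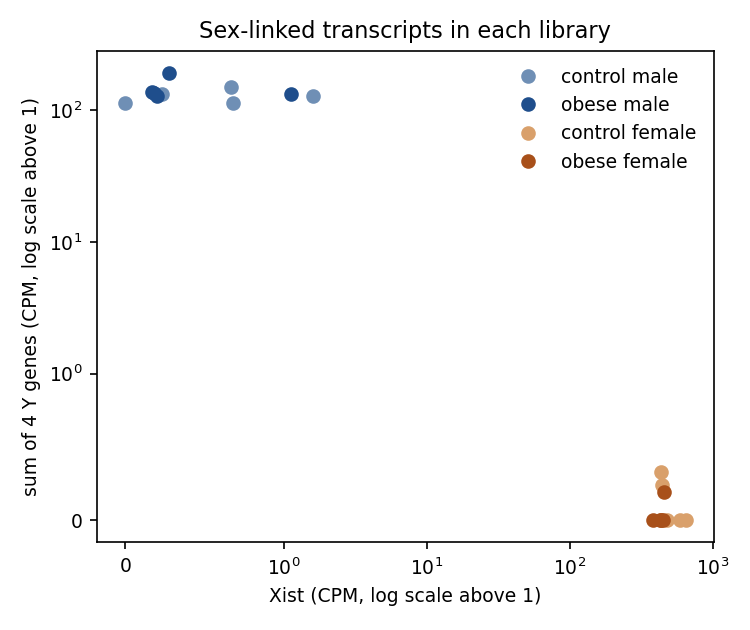
Xist against the sum of the Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y, in CPM on axes that are logarithmic above 1, with 1 point per library colored by group. The 10 female libraries sit at 383.3 CPM of Xist or more, and the 10 male libraries at 1.59 or less.

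Most libraries carried the transcripts of heart muscle at high levels, and 5 of the 20 also, or instead, were rich in those of lung, liver or thymus by the rule used here. Control male 4 and obese male 1 held lung markers at 19940 and 24840 summed CPM, led by Sftpc, which encodes a surfactant protein, at 10183 and 11787 CPM. Their ventricular muscle markers summed to 966.3 and 1083 CPM, against 30376 to 36711 in the other 4 control males and 31280 to 37169 in the other 4 obese males. Myh6, the alpha myosin heavy chain of heart muscle, was at 104.7 and 115.1 CPM in them, against a median of 11609 in the 17 libraries that are not lung-rich. Control female 4 held both, with 11424 summed CPM of lung markers and 14866 of ventricular markers. Control female 3 held liver markers at 68346 summed CPM, with Alb, the serum albumin gene, at 28481 CPM, and also the highest neutrophil markers, at 2044 summed CPM. Control female 5 held lymphocyte and thymus markers at 1329 summed CPM, with Rag1, which cuts antigen receptor genes, at 314.7 CPM. The medians over the 20 libraries were 7.08 summed CPM for lung, 1079 for liver and 3.92 for lymphocyte and thymus markers. Of the markers in these lists, 1 of 11 lung genes, 12 of 13 liver genes and 1 of 15 lymphocyte and thymus genes reached a median of 1 CPM in the other 15 libraries. Of the 5 libraries 4 come from control dams, 3 of them females, so these transcripts are unevenly spread over diet and sex in the comparisons that follow. The libraries kept are not free of other tissues. Control female 2 held Myh8, a skeletal muscle myosin, at 236.4 CPM, cartilage markers at 325.1 summed CPM and liver markers at 6437, and obese female 3 held liver markers at 6863. Without the 3 libraries rich in lung transcripts, 4 control male, 4 obese male, 4 control female and 5 obese female libraries remain. Without all 5, only 2 control females remain, so the female contrast then sets 2 libraries against 5.

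**Figure D2:**
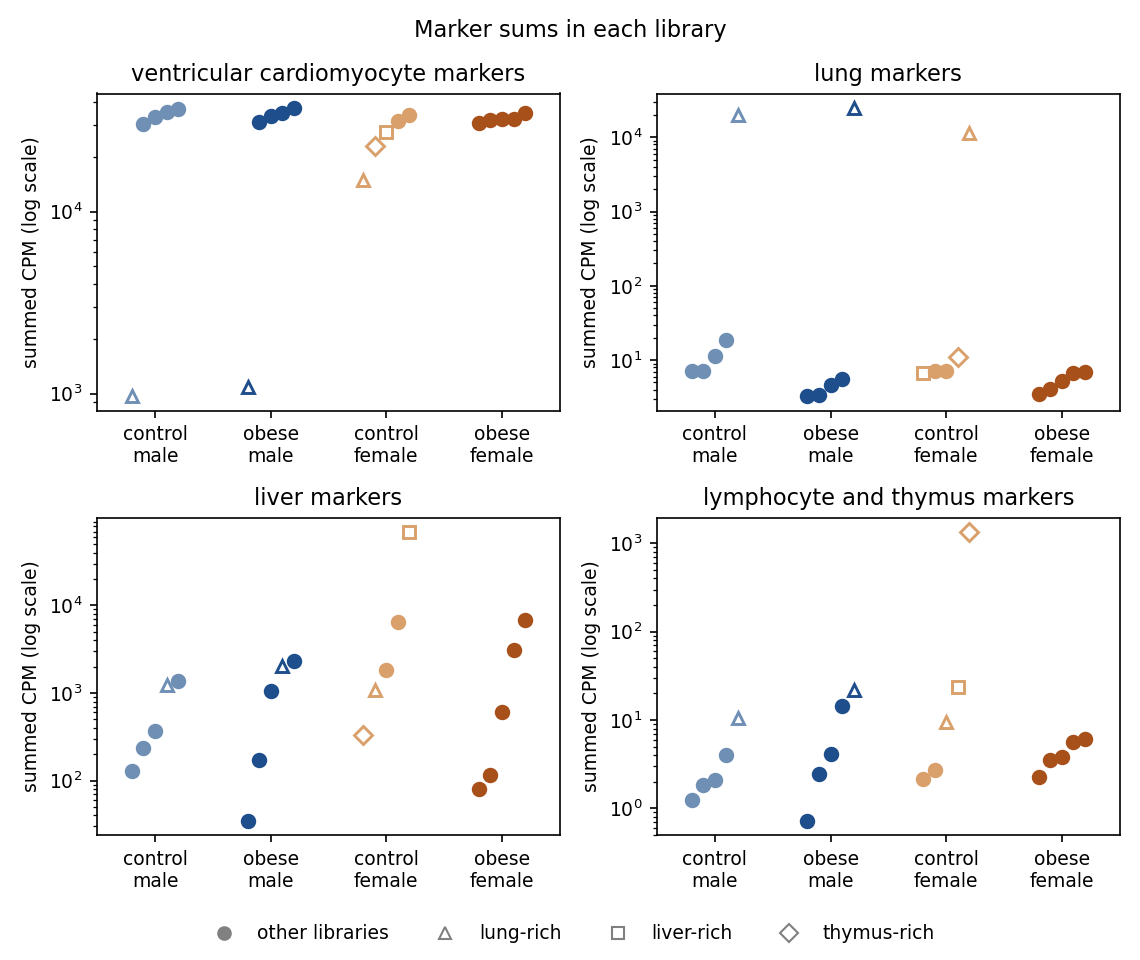
Summed CPM of ventricular, lung, liver, and lymphocyte and thymus markers on logarithmic axes, with 1 point per library in 4 groups of 5. Open triangles mark the lung-rich libraries, the open square the liver-rich library at 68346 and the open diamond the thymus-rich library at 1329.

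The first question was whether maternal obesity changed transcript levels in the fetal heart over both sexes. Genes of cholesterol synthesis and uptake were lower in fetuses of obese dams, with a median log2 change of -0.35 and 22 of the 23 measured members below 0. The list's adjusted p was 9.83e-17 with the preset correlation of camera and 0.330 with an estimated correlation. Its mean log2 CPM, obese minus control, was -0.34 ± 0.14 (SE), and -0.16 ± 0.13 (SE) without the 5 libraries rich in other transcripts, a set chosen after the data were seen. The transcript of Srebf2, the transcription factor that switches this pathway on, averaged 178.7 ± 16.8 CPM (SD, n = 10) in fetuses of control dams and 151.8 ± 12.3 (SD, n = 10) in those of obese dams, a log2 change of -0.24 ± 0.06 (SE). Cd36, a fatty acid transporter of heart muscle and endothelium, averaged 397.8 ± 61.4 CPM in fetuses of control dams and 512.0 ± 44.2 in those of obese dams (SD, n = 10 each). Adgrl4, a receptor of endothelial cells, averaged 29.4 ± 2.91 and 37.0 ± 3.93 CPM (SD, n = 10 each).

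Of these, no single gene passed over all genes tested. With edgeR 0 of 12924 genes had an adjusted p under 0.05, the smallest being 0.991, while 569 had an unadjusted p under 0.05, which is 4.40% of those tested. DESeq2 also gave 0 genes, with 661 at an unadjusted p under 0.05, and limma-voom 0 with 556. Without the 3 lung-rich libraries 2 of 12789 genes passed with edgeR, and 1552 had an unadjusted p under 0.05. Without all 5 other-organ libraries 3 of 13096 passed, and 1279 had an unadjusted p under 0.05. Both sets were added after the data were seen. More genes thus had a small unadjusted p in these sets than over all 20 libraries. Adjusted over the list alone, 2 of 23 cholesterol genes passed, among them Srebf2 with an adjusted p of 0.0253, and Cd36 passed as 1 of 27 genes of fatty acid uptake and oxidation and as 1 of 25 PPAR targets, with adjusted p of 0.0274 and 0.0254.

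Among genes with the smallest p in this contrast, which did not pass over all genes, those higher in fetuses of obese dams were Adgrl4 at a log2 change of 0.33, Rnf103, a ubiquitin ligase, at 0.24, Ralgapa2, a subunit of a complex that switches off Ral GTPases, at 0.30, Cd36 at 0.36 and Syt7, a calcium sensor of membrane fusion, at 0.37. Lower were Mtrr, which keeps methionine synthase active, at -0.29, Samd14 at -0.41, Myo9b, an unconventional myosin, at -0.22, Mdn1, which matures the large ribosomal subunit, at -0.41 and Cdh24, a cadherin, at -0.53. Mtrr averaged 26.4 ± 1.78 CPM in fetuses of control dams and 21.5 ± 2.20 in those of obese dams (SD, n = 10 each). On mm10, Adgrl4 lies on chromosome 3 at 151437882 to 151545081, Cd36 on chromosome 5 at 17781690 to 17888959, Mtrr on chromosome 13 at 68560780 to 68582169 and Srebf2 on chromosome 15 at 82147269 to 82204960.

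**Figure D3:**
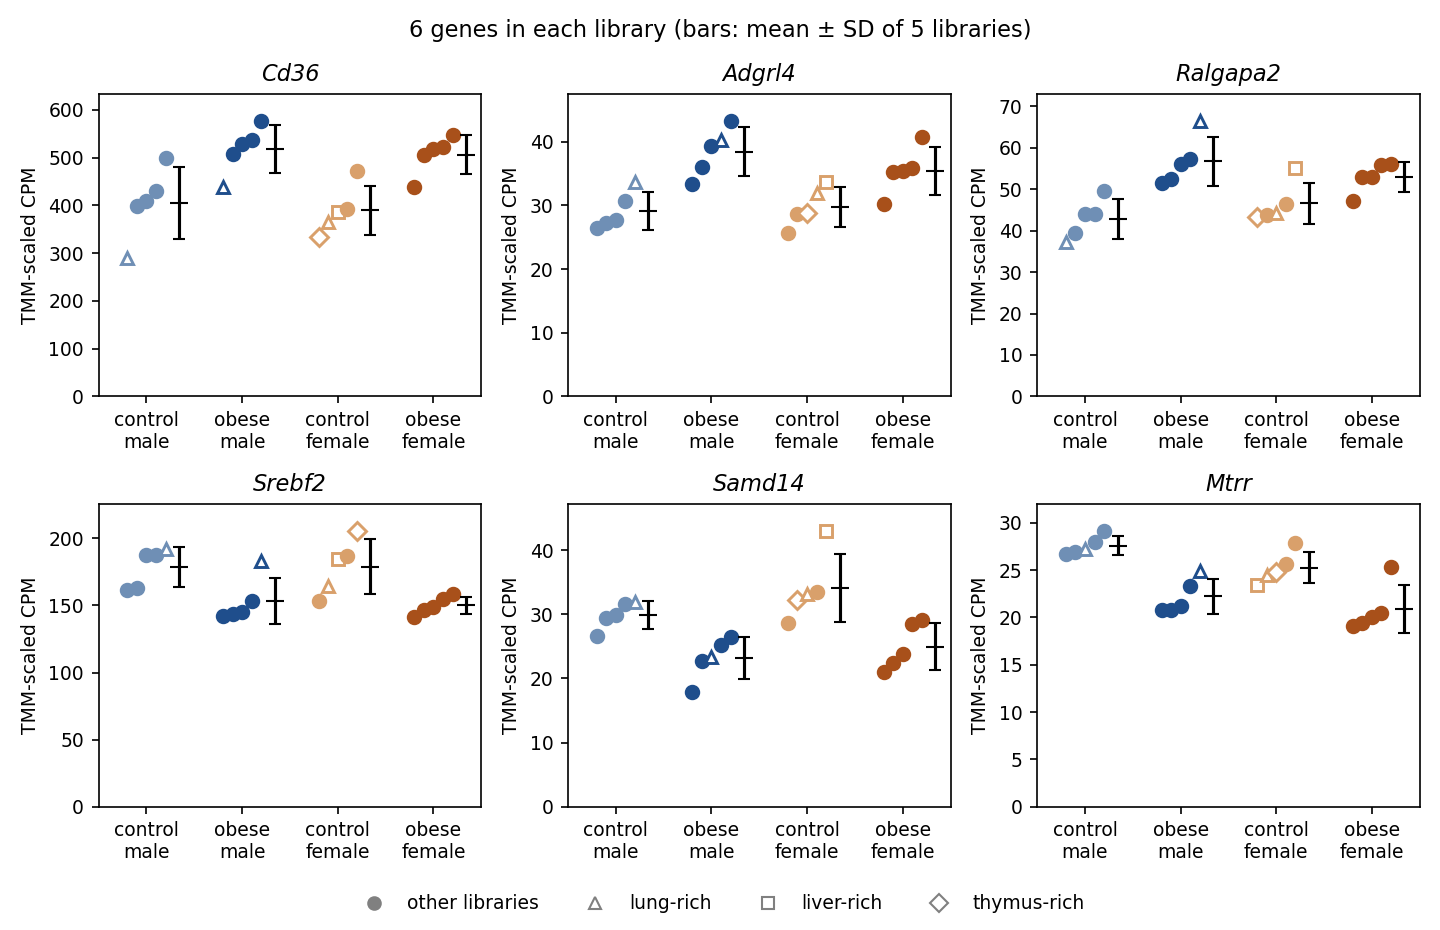
TMM-scaled CPM of Cd36, Adgrl4, Ralgapa2, Srebf2, Samd14 and Mtrr, with 1 point per library in 4 groups and the mean ± SD of 5 libraries beside them. Cd36 averages 405.5 and 390.0 CPM in male and female fetuses of control dams and 517.8 and 506.2 in those of obese dams, and open symbols mark the 5 libraries rich in transcripts of another organ.

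Over both sexes camera with its preset correlation called 22 of the 52 lists, 16 higher and 6 lower. With an estimated correlation 0 of the 22 held, and fry also called 0. Cholesterol synthesis had the smallest adjusted p with the preset, and an exact permutation test of its mean log2 CPM gave p = 0.0140, or 0.382 adjusted over the 52 lists. Genes of the endoplasmic reticulum stress response were also lower, with 21 of 28 below 0 and a median of -0.15, among them the protein disulfide isomerases Pdia4 at -0.31 and Pdia6 at -0.25, and Sdf2l1 at -0.35. Its adjusted p was 0.00144 with the preset and 0.547 with an estimated correlation, and its exact permutation p was 0.0147, or 0.382 adjusted. These transcripts were highest in the lung-rich control male 4, at 5427.9 summed CPM. Without it the adjusted p with the preset was 0.00608 and Pdia4 was at -0.21. Over 17 libraries the median was -0.092, and over 15 it was -0.043 with an adjusted p of 0.107.

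Lists of energy supply were higher. In the nuclear-encoded respiratory chain 72 of 73 members were above 0 with a median of 0.21, for example the complex I subunits Ndufa3 at 0.24, Ndufv3 at 0.27 and Ndufa7 at 0.16. Its adjusted p was 1.22e-07 with the preset and 0.812 with an estimated correlation. Of the genes of fatty acid uptake and oxidation 25 of 27 were above 0 with a median of 0.18. Cd36 and the transporter Slc27a1, at 0.22, were higher while the transporter Slc27a6 was at -2.03 ± 1.19 (SE), or 0.054 without the lung-rich control male 4. Over 15 libraries Cd36 was at 0.27 and Slc27a1 at 0.089. The adjusted p of the list was 0.000113, or 0.812 with an estimated correlation. PPAR targets, which lipids switch on, had 17 of 25 above 0, with Acot2, a mitochondrial thioesterase, at 0.37 and Pdk4, which holds back glucose oxidation, at 0.55. Their adjusted p was 0.00144, or 0.812 with an estimated correlation. In the autophagy and atrophy list 20 of 21 were above 0, with the cargo receptor Sqstm1 at 0.21, Wipi1 at 0.27 and the mitophagy receptor Bnip3 at 0.45. That adjusted p was 0.000113, or 0.176 with an estimated correlation. Over 15 libraries Sqstm1, Wipi1 and Bnip3 were at 0.15, 0.095 and 0.43. All 25 sarcomere genes were above 0 with a median of 0.22, such as Nebl at 0.23, Myom2 at 0.39 and Tpm1 at 0.24, with an adjusted p of 0.00812, or 0.812 with an estimated correlation. Respiratory chain and sarcomere genes are abundant in heart muscle, and 4 of the 5 libraries rich in transcripts of another organ are from control dams. Without control male 4 the adjusted p with the preset was 0.565 for the respiratory chain, 0.199 for fatty acid uptake and 0.517 for the sarcomere, with Ndufa3 at 0.14, Ndufv3 at 0.15, Ndufa7 at 0.084, Nebl at 0.12, Myom2 at 0.23 and Tpm1 at 0.099. Without the 3 lung-rich libraries the medians were 0.13 for the respiratory chain, 0.12 for fatty acid uptake and 0.14 for the sarcomere.

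Lists of liver and red blood cell transcripts were lower. All 12 liver genes were below 0 with a median of -1.09, among them Trf at -1.21, Ahsg at -1.08 and Fgg at -1.21, which encode proteins that the liver secretes into plasma. The adjusted p was 0.00294, or 0.812 with an estimated correlation, and the control mean of Trf, 1809 ± 4552 CPM (SD, n = 10), holds the liver-rich library. Without control female 3 the changes of Trf, Ahsg and Fgg were 0.091, 0.42 and 0.28, and the list's adjusted p with the preset was 0.935. All 12 erythroid genes were below 0 with a median of -0.57, with the globins Hbb-bs and Hbb-b1 at -0.57 each and Trim10 at -1.06. Their adjusted p was 0.00233, or 0.812 with an estimated correlation. The erythroid markers were highest in control female 3, at 25255 summed CPM, and without it the adjusted p was 0.719 and Trim10 was at -0.12.

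**Figure D4:**
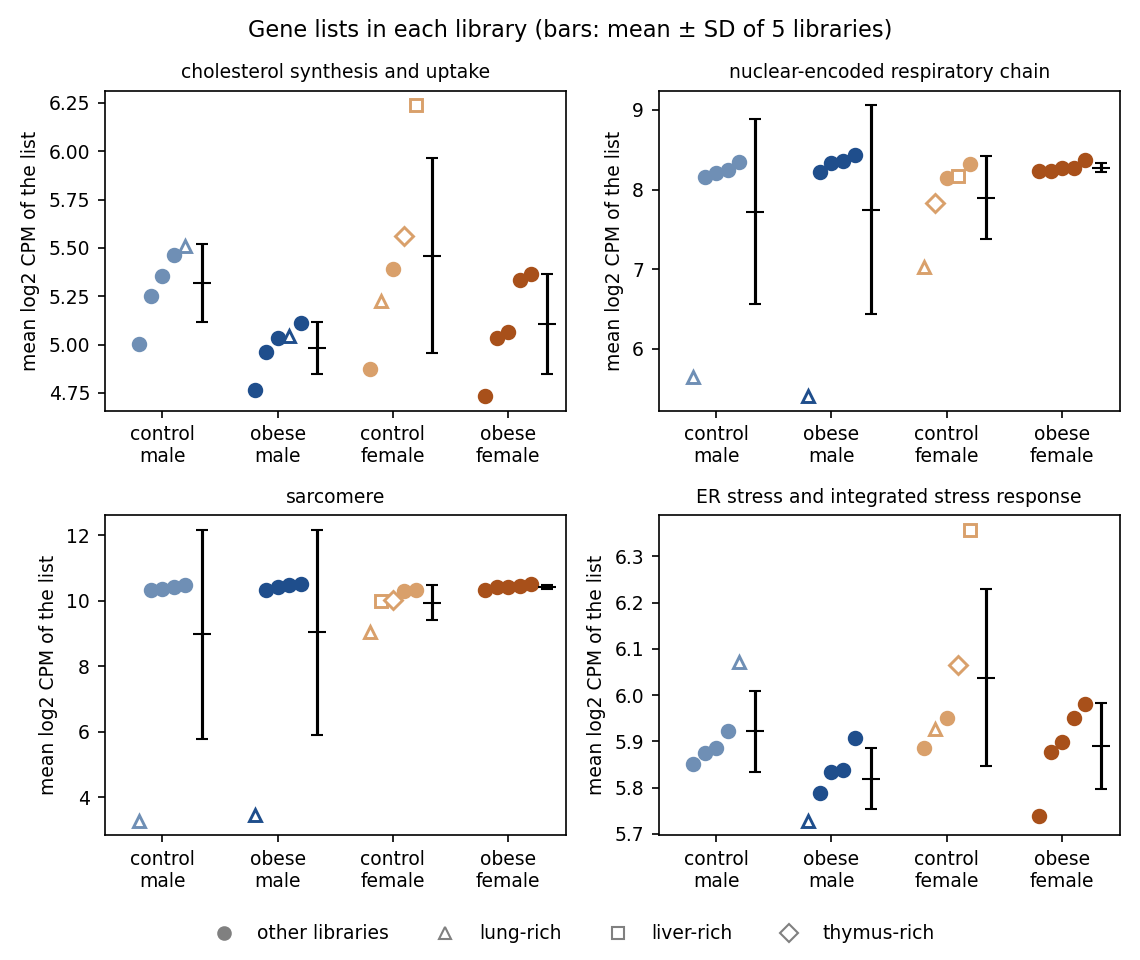
Mean log2 CPM of 4 gene lists with 1 point per library and the mean ± SD of 5 libraries, where open symbols mark libraries rich in transcripts of another organ. For cholesterol synthesis and uptake the means are 5.32 and 5.46 in male and female fetuses of control dams and 4.98 and 5.11 in those of obese dams.

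Of a panel of cardiac and metabolic genes fixed in advance, those reported here showed no change past the threshold, with adjusted p of 0.991 or above in edgeR. Nppa and Nppb, the natriuretic peptides that mark cardiac load, were at log2 changes of 0.01 ± 0.82 and 0.37 ± 0.70 (SE), and Nppb was at 0.13 without obese male 3. The myosin heavy chains Myh6 and Myh7 were at 0.30 ± 0.61 and 0.12 ± 0.63 (SE), and their CPM averaged 9021 ± 3850 and 13603 ± 5923 in fetuses of control dams (SD, n = 10). They were at 0.14 and -0.035 without the lung-rich control male 4, and at 0.46 and 0.28 without the lung-rich obese male 1. Acta1 and Ankrd1, which rise in strained muscle, were both at 0.41 ± 0.64 (SE), and Acta1 was at -0.18 without obese male 5 and 0.90 without control female 2. Among metabolic genes Pdk4 was at 0.55 ± 0.28, Angptl4, an inhibitor of lipoprotein lipase, at 0.36 ± 0.26 and Cpt1a, which admits fatty acids to mitochondria, at 0.05 ± 0.10 (SE). Pdk4 was at 0.36 without obese female 2 or without obese male 2. The glucose transporters Slc2a1 and Slc2a4 were at -0.01 ± 0.21 and 0.28 ± 0.46 (SE). Slc2a4 was at 0.13 without control male 4 and 0.44 without obese male 1. The fetal growth factor Igf2, collagen Col1a1, the adiponectin receptor Adipor1 and the insulin receptor Insr were at 0.02 ± 0.35, -0.05 ± 0.15, 0.07 ± 0.10 and 0.10 ± 0.10 (SE). Insr was at 0.043 without control male 4. Ucp3 was too low to test. For several of these genes the SE is smaller without the lung-rich libraries. Over the 17 others, a set chosen after the data were seen, Myh6 was at 0.23 ± 0.06 with an adjusted p of 0.188 in edgeR, Myh7 at 0.05 ± 0.08, Nppa at -0.11 ± 0.42, Nppb at 0.26 ± 0.22, Ankrd1 at 0.32 ± 0.16, Slc2a4 at 0.17 ± 0.07 and Igf2 at -0.05 ± 0.06 (SE). Angptl4 was at 0.33 ± 0.28 (SE) over 17 libraries, and over 15 at 0.66 ± 0.20 (SE) with an adjusted p of 0.228 in edgeR. Over the same 15 libraries Myh6 was at 0.19 ± 0.06, Myh7 at -0.02 ± 0.06 and Slc2a4 at 0.10 ± 0.07 (SE). Nppa was then at -0.24 ± 0.46, Nppb at 0.31 ± 0.27, Ankrd1 at 0.42 ± 0.20 and Igf2 at -0.06 ± 0.05 (SE). None of these passed.

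In male fetuses the same question was asked with 5 libraries against 5. Cholesterol genes were lower here too, with 21 of 23 below 0 and a median of -0.35. Msmo1 and Srebf2 were at log2 changes of -0.69 ± 0.23 and -0.22 ± 0.09 (SE), and Msmo1, which removes methyl groups from sterols, averaged 46.5 ± 5.93 CPM in control males and 28.8 ± 5.55 in obese males (SD, n = 5 each). The adjusted p of the list was 1.58e-14, or 0.220 with an estimated correlation, and the exact permutation p was 0.0317, or 0.649 adjusted. Interferon-stimulated genes were higher in 28 of 29 cases with a median of 0.34, with the antiviral GTPase Mx2 at 0.88, Gbp3 at 0.61 and Bst2, which tethers virus particles, at 0.44. Their adjusted p was 8.11e-08, or 0.477 with an estimated correlation. The lung-rich obese male 1 held the most of these transcripts, 1243.6 summed CPM, and without it the adjusted p was 0.466. Over 17 libraries, without 1 lung-rich male of each group, 22 of 28 were higher with a median of 0.19 and an adjusted p of 0.0179, or 0.769 with an estimated correlation, and Mx2 was at 0.72.

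Autophagy genes were higher in males in 20 of 21 cases, with a median of 0.15, and this was the only list of 17 called in males that held with an estimated correlation, at an adjusted p of 0.0219, against 8.11e-08 with the preset. With fry its adjusted p was 0.106, so it did not pass there. Sqstm1 averaged 217.3 ± 7.17 CPM in control males and 262.1 ± 35.0 in obese males (SD, n = 5 each), Gabarapl1, which builds autophagosomes, was at 0.34 and Becn1, which starts them, at 0.13. Without the lung-rich obese male 1 Gabarapl1 was at 0.18. The exact permutation p of this list was 0.381 over 5 against 5, with 1 lung-rich male in each group, and 0.0286 over 4 against 4 without them, or 0.495 adjusted, where 0.0286 is the smallest p that 70 arrangements allow. Without those libraries its adjusted p with an estimated correlation was 0.519.

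Cell cycle genes were lower in males in 39 of 42 cases with a median of -0.14, such as E2f1, which switches on genes of DNA synthesis, at -0.55, the helicase subunit Mcm4 at -0.43 and the cyclin Ccne2 at -0.51. The adjusted p was 1.78e-08, or 0.650 with an estimated correlation. Over 17 libraries, without 1 lung-rich male of each group, E2f1 was at -0.49, Mcm4 at -0.32 and Ccne2 at -0.40. Without the lung-rich obese male 1 alone, with the lung-rich control male 4 kept, the adjusted p with the preset was 0.280. E2f1 was then at -0.35, Mcm4 at -0.27 and Ccne2 at -0.31. All 7 skeletal muscle genes left by the filter were higher, with the myosin light chain Mylpf at 3.47, the troponin Tnnt3 at 2.65 and the perinatal myosin Myh8 at 2.43, and an adjusted p of 0.0376, or 0.650 with an estimated correlation. Obese male 5 held 214.3 CPM of Myh8 and 89.8 of Mylpf, and without it the changes were -0.22 for Mylpf, -0.54 for Tnnt3 and -0.52 for Myh8.

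By edgeR 0 of 12924 genes passed in males, with 263 at an unadjusted p under 0.05, and DESeq2 and limma-voom also gave 0, with 275 and 262. The genes with the smallest p were Rnf103 at 0.33, Ralgapa2 at 0.40, Adgrl4 at 0.40, the zinc finger gene Zfp984 at 0.46 and the transcription factor Foxn3 at 0.85. Lower were Hps6, of a complex that builds lysosome-related organelles, at -0.50, Mtrr at -0.31, Gmppb, which makes GDP-mannose, at -0.48, Lrrc75b at -1.24 and Ruvbl2, a helicase of chromatin remodelers, at -0.31. Camera called 13 lists higher and 4 lower in males. Without control male 4, which is lung-rich, it called 27, of which 16 were lower, and without obese male 3 it called 11. Over 17 libraries edgeR gave 0 genes in males, with 586 at an unadjusted p under 0.05, and over 15 libraries 0 with 889.

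In female fetuses lists of energy supply and contraction were higher. In the respiratory chain 72 of 73 genes were above 0 with a median of 0.32, among them Ndufv3 at 0.40, Ndufs8 at 0.36 and Ndufa3 at 0.30. The adjusted p was 5.70e-11, or 0.739 with an estimated correlation. Mitochondrial ribosomal proteins were above 0 in 58 of 60 cases with a median of 0.17, with Mrpl11 at 0.40, Mrpl43 at 0.24 and Mrps31 at 0.43, and an adjusted p of 4.08e-08, or 0.739 with an estimated correlation. All 25 sarcomere genes were above 0 with a median of 0.42, with Tpm1 at 0.46, Tcap at 0.49 and Myoz2 at 0.59, and an adjusted p of 0.000853, or 0.788 with an estimated correlation. Tpm1 averaged 3718 ± 1076 CPM in control females and 5129 ± 207 in obese females (SD, n = 5 each). Of the control females 3 of 5, and of the obese females 0 of 5, are rich in lung, liver or thymus transcripts by the rule used here. Over the other 2 control and 5 obese females, which include control female 2 with its skeletal muscle and cartilage transcripts, the medians were 0.04 for the respiratory chain, 0.06 for mitochondrial ribosomal proteins and 0.10 for the sarcomere. Without the lung-rich control female 4 alone Ndufv3 was at 0.25, Mrpl43 at 0.13 and Tcap at 0.30.

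Cholesterol genes were lower in females in 21 of 23 cases, with a median of -0.38. Srebf2 was at -0.25 ± 0.09 and Sc5d, an enzyme of sterol synthesis, at -1.01 ± 0.37 (SE). The list's adjusted p was 3.93e-07, or 0.739 with an estimated correlation, and its exact permutation p was 0.183. Without control female 3 the adjusted p with the preset was 0.0505 and Sc5d was at -0.32. Over the 2 control and 5 obese females the median was -0.04, with 10 of 24 genes above 0. The largest negative values belonged to transcripts of other tissues. All 12 liver genes had a median of -3.00, with Ahsg at -3.00, Serpina1a at -3.13 and Trf at -3.07, and an adjusted p of 3.30e-05, or 0.739 with an estimated correlation. Without control female 3 these were -0.0041, -0.25 and -0.46, and the adjusted p was 0.316. All 12 erythroid genes were below 0 with a median of -0.78, with Hemgn at -3.32, Trim10 at -2.32 and the band 3 anion exchanger Slc4a1 at -2.19, and an adjusted p of 0.000210, or 0.739 with an estimated correlation. Those values were -0.84, -0.46 and 0.18 without control female 3, where the adjusted p was 0.622. All 7 neutrophil genes were below 0 with a median of -3.02, with the myeloperoxidase Mpo at -3.64, S100a8 at -3.09 and S100a9 at -2.87. Their adjusted p was 0.00222, or 0.739 with an estimated correlation, and all 7 passed when adjusted over the list alone. Without control female 3, which is liver-rich, the neutrophil list's adjusted p was 0.984 and S100a9 was at 0.15. Mpo was then at -1.08 and S100a8 at -0.26.

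By edgeR 0 of 12924 genes passed in females, with 652 at an unadjusted p under 0.05 and a smallest adjusted p of 0.918. DESeq2 and limma-voom also gave 0, with 895 and 380. Higher with the smallest p were Bcl7b, a subunit of a chromatin remodeler, at 0.34, Stbd1, which binds glycogen, at 0.41, Syt7 at 0.49, Mxra7 at 0.33 and BC003331 at 0.32. Stbd1 averaged 128.6 ± 18.3 CPM in control females and 170.5 ± 9.34 in obese females (SD, n = 5 each). Lower were Myo9b at -0.33, Parvg at -2.77, Pstpip2 at -1.07, the lymphoid transcription factor Ikzf1 at -3.81 and Aqp11 at -2.46, where Ikzf1 averaged 32.7 ± 49.4 CPM in control females and 2.35 ± 0.715 in obese females (SD, n = 5 each). Without the thymus-rich control female 5, Ikzf1 was at -2.25 and Parvg at -1.47, and over 15 libraries Ikzf1, Parvg and Aqp11 were at 0.39, -0.68 and -0.93. Camera called 10 lists higher and 7 lower in females. Over 17 libraries edgeR gave 0 genes in females, with 1843 of 12789 at an unadjusted p under 0.05, and over 15 libraries 0 with 749 of 13096.

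The next question was whether the diet effect differed between male and female fetuses. Transcripts of other tissues differed most, with medians for the male effect minus the female effect of 3.83 in 12 liver genes, 3.99 in 7 neutrophil genes and 3.35 in 7 skeletal muscle genes. Examples are Ahsg at 3.85, Serpina1a at 4.06 and Apob at 4.09 for liver, Mpo at 5.36, S100a8 at 4.03 and S100a9 at 3.72 for neutrophils, and Mylpf at 7.03, Tnnt3 at 5.61 and Myh8 at 4.76 for skeletal muscle. Their adjusted p were 3.05e-06, 3.41e-06 and 0.0210 with the preset, and 0.729, 0.729 and 0.754 with an estimated correlation. Adjusted over the list alone 6 of 7 neutrophil and 4 of 7 skeletal muscle genes passed, and 0 of 12 liver genes. Control female 3 holds the liver and neutrophil transcripts, and control female 2 and obese male 5 the skeletal muscle transcripts, with 236.4 and 214.3 CPM of Myh8. Without control female 3 the values were 0.85 for Ahsg, 1.19 for Serpina1a, 1.17 for Apob, 2.81 for Mpo, 1.22 for S100a8 and 0.72 for S100a9, and the adjusted p with the preset were 0.0732 for liver and 0.0418 for neutrophil genes. Without control female 2 Mylpf, Tnnt3 and Myh8 were at 4.11, 3.24 and 1.98. The skeletal muscle list had an adjusted p of 0.341 without control female 2, 0.479 without obese male 5 and 0.529 without control male 4.

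Respiratory chain genes had a lower diet effect in males than in females in 72 of 73 cases, with a median of -0.24, for example Ndufb3 at -0.29, Ndufs8 at -0.30 and Ndufa12 at -0.35. The adjusted p was 3.15e-06, or 0.754 with an estimated correlation, and without the 5 other-organ libraries the median was 0.05. Without the lung-rich obese male 1 the adjusted p was 0.157, with Ndufb3 at -0.078, Ndufs8 at -0.056 and Ndufa12 at -0.075. Without the lung-rich control male 4 it was 1.47e-14, with Ndufb3 at -0.50, Ndufs8 at -0.52 and Ndufa12 at -0.62. Cytosolic ribosomal proteins had a higher effect in males in 71 of 77 cases with a median of 0.16, with Rps10 at 0.33, Rpl19 at 0.25 and Rps23 at 0.32. The adjusted p was 3.41e-06, or 0.754 with an estimated correlation. These transcripts were highest in the lung-rich control male 4 and obese male 1, at 27595 and 24880 summed CPM. The 17 libraries that are not lung-rich ran from 16898 to 20568. Over 15 libraries Rps10, Rpl19 and Rps23 were at 0.32, 0.30 and 0.36. Camera called 19 lists in this contrast, 10 higher and 9 lower, and 0 held with an estimated correlation or with fry.

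For single genes edgeR gave 0 of 12924 with a diet effect that differed between sexes, with 247 at an unadjusted p under 0.05, and DESeq2 and limma-voom gave 0 with 404 and 105. The smallest p belonged to Rb1, the retinoblastoma tumor suppressor, at 0.69 ± 0.14 (SE). It averaged 20.1 ± 1.27 CPM in control males, 25.7 ± 2.06 in obese males, 27.2 ± 4.26 in control females and 21.4 ± 1.11 in obese females (SD, n = 5 each). Also above 0 were Mmp9 at 4.66, Man1a at 0.96, Acp5 at 3.68, Mylpf at 7.03 and Pip4k2a at 0.92. Over 15 libraries Man1a was at 0.39 and Pip4k2a at 0.43, and without obese male 5 Mylpf was at 3.33. Below 0 were Mmab at -0.48, Rtl8b at -0.38, the connexin Gjc1 at -0.38, Nsmce3 at -0.51, Praf2 at -0.46 and Ovca2 at -0.35. In the same order these were at -0.44, -0.18, -0.26, -0.44, -0.25 and -0.23 over 15 libraries.

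Across the 12924 genes, which are not independent replicates, the log2 changes of males and females had a Pearson correlation of -0.245 and a Spearman correlation of 0.0323, and 52.98% of genes had the same sign. The correlation was 0.556 without obese male 1 and -0.707 without control male 4, so each of these lung-rich libraries turned or moved it. Without all 5 other-organ libraries it was -0.256.

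The last comparison was between male and female fetuses over both diets. Besides the 4 Y-linked genes Eif2s3y, Ddx3y, Kdm5d and Uty, 3 genes passed with edgeR, and all 3 are X-linked and were lower in males. Xist changed by -9.89 ± 0.33, the histone demethylase Kdm5c by -0.59 ± 0.06 and the translation factor Eif2s3x by -0.70 ± 0.09 (SE), with adjusted p of 8.80e-13, 6.39e-05 and 0.000401. DESeq2 and limma-voom gave the same count of 3. Kdm6a, another X-linked demethylase, was at -0.72 ± 0.19 (SE) and passed without the 3 lung-rich libraries, at -0.95 with an adjusted p of 0.000182. Rnf217 at 0.32 and Cavin3, a protein of caveolae, at 0.24 were higher in males without passing, and Upb1 at -1.99 and the interferon-inducible Ifi203 at -0.54 lower. Without the liver-rich control female 3 Upb1 was at -1.06.

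Of 10 measured X-linked genes that escape inactivation 9 were lower in males and 7 passed when adjusted over the list alone, with a median of -0.39. This list and that of the Y-linked genes held with an estimated correlation, at adjusted p of 2.79e-11 and 5.75e-16, among the 22 that camera called with the preset, 4 higher and 18 lower. All 12 erythroid genes were lower in males with a median of -0.89, and all 12 passed when adjusted over the list alone. They are not 12 separate readings, since Hbb-b2 and Hbb-bt had the same value, -0.89, and Hbb-bs and Hbb-b1 were both at -0.77. Hba-a1, an alpha globin gene, averaged 2396 ± 1104 CPM in control males and 2009 ± 820.5 in obese males, against 4611 ± 2434 in control females and 3068 ± 1455 in obese females (SD, n = 5 each), with a log2 difference of -0.78 ± 0.30 (SE). Its near-identical copy Hba-a2 was at -0.76 and Slc4a1 at -1.84, or -0.66 for Slc4a1 without the liver-rich control female 3, which holds the most erythroid markers. The erythroid list's adjusted p was 1.88e-11 with the preset and 0.344 with an estimated correlation, and 0.0499 with an estimated correlation over the 15 libraries not rich in transcripts of another organ. Without control female 3 it was 4.46e-08 with the preset. Liver genes moved the same way, with all 12 lower in males at a median of -2.99 and 11 passing when adjusted over the list alone, among them Alb at -3.35 and Afp at -3.14. Over 15 libraries the liver median was -1.96 and 0 passed. Among the called lists, that of fatty acid uptake and oxidation had a median of -0.10 and was called lower in males, while its mean was 0.0049.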

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

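The tests of lung tissue, of maternal diet as a source of lung transcripts, and of the sets without libraries rich in another organ's transcripts were chosen after the libraries had been seen, as were the tests of the shift of list means on thinning, while the tests of the means with libraries thinned to the smallest total were written before their results.

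Over 10 quantities and 40 groups of 5, a single library lay far from the other 4 of its group 14 times. Chance gives about 1 in 20 groups for normally distributed values, which summed CPM need not be. Of the 14, 11 fell in the 5 libraries rich in another organ's transcripts. Those 5 were picked by their lung, liver and thymus sums, so for these sums the place was fixed in advance. Lung markers summed to 19940 CPM in control male 4 (others 7.17 to 18.9), 24840 in obese male 1 (3.26 to 5.63) and 11424 in control female 4 (6.63 to 10.9). Ventricular markers summed to 966.3 CPM in control male 4 (others 30376 to 36711) and 1083 in obese male 1 (31280 to 37169). Skeletal muscle markers, which include genes that heart muscle also expresses, summed to 33.1 CPM in control male 4 (3411 to 3581) and 29.0 in obese male 1 (3444 to 4508). Neutrophil markers summed to 101.4 CPM in control male 4 (22.3 to 37.0) and 2044 in control female 3 (19.9 to 94.4). Liver markers summed to 68346 CPM in control female 3 (333.9 to 6437), and lymphocyte and thymus markers to 1329 in control female 5 (2.15 to 23.9). Cartilage markers summed to 325.1 CPM in control female 2 (38.1 to 88.0) and 137.1 in obese male 5 (47.8 to 67.5). Control male 3 held 1.478 M estimated counts, against 3.765 to 4.498 M in the other control males.

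The diet effect differed between sexes, by the preset test of the difference itself, in 5 of the lists described. The medians of the male effect minus the female effect were 3.83 for liver, 3.99 for neutrophil, 3.35 for skeletal muscle, -0.24 for respiratory chain and 0.16 for cytosolic ribosomal protein genes. With an estimated correlation between genes the adjusted p of these lists ran from 0.729 to 0.754. The preset calls of liver, skeletal muscle and respiratory chain genes end in at least 1 fit without a single library.

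A candidate explanation for the 3 lung-rich libraries is lung tissue in the sample, alone or beside heart. Sftpc was at 10183 CPM in control male 4, 11787 in obese male 1 and 5523 in control female 4, against at most 6.77 in the other 17 libraries, and Sftpb at 2302, 2837 and 1282. Of the 11 lung markers 1 reached a median of 1 CPM in the 15 libraries not rich in transcripts of another organ and 0 are in another list. The deviation of control female 4 from those 15 libraries followed the mean deviation of the other 2 with a Pearson correlation of 0.862 across 12924 genes, against -0.0981 to 0.162 for the 15. If those 2 libraries are taken as all lung, the lung share of control female 4 came to 51.0% from lung markers and 57.2% from ventricular markers. No lung sample in the series can check that assumption. Maternal diet as the source is argued against, since 2 of the 3 libraries come from control dams. An exchange of sample names with lungs stays open for control male 4 and obese male 1, because no lung sample is in the series. Control female 4 also held ventricular markers, at 14866 summed CPM, which argues against an exchange with lung alone for that library.

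A second pattern is the lower mean of cholesterol genes in fetuses of obese dams, at a log2 difference of -0.34 over 20 libraries. Thinned to the smallest total it was -0.343 ± 0.129 (SE), and thinning moved the difference by 0.000298 ± 0.0202 (SE), which argue against sequencing depth. Without the 5 libraries rich in transcripts of other organs it was -0.164 ± 0.126 (SE), against 0.172 for one part in 2 of the full size, so RNA of other organs and an effect of maternal diet cannot be told apart here, and by sex it was -0.30 ± 0.16 in males (-0.33 over all 10) and -0.028 ± 0.19 in females (-0.35) (SE). Liver is a hypothesis for part of it, from 13 liver markers of which 12 reach a median of 1 CPM in the 15 libraries and 0 are in another list, and control female 3, with Alb at 28481 CPM and Afp at 6337, also had the highest list mean. A diet effect on the heart itself stays open and was not tested apart from these.

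The last pattern weighed is the higher respiratory chain mean in females of obese dams, at 0.377 over 10 female libraries. Over the 7 female libraries not rich in transcripts of lung, liver or thymus it was 0.0450 ± 0.0679 (SE), so RNA of other organs in 3 control females may account for most of it. Thinned to the smallest total it was 0.384 ± 0.574 (SE), an error pooled over the 4 groups that excludes nothing. Measured within each library, thinning moved the difference by 0.00738 ± 0.00560 (SE), where sequencing depth as the source of one part in 2 of it needs -0.188 or lower, which argues against depth. An effect of maternal diet of the size left over the 7 libraries stays open.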

How the results depend on the processing

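Fits without the 3 lung-rich or all 5 other-organ libraries were chosen after the data were seen. The counts of genes changed by maternal obesity stayed at 0 under each alternative for males, females and the difference between sexes (263, 652 and 247 at an unadjusted p under 0.05 with edgeR, 275, 895 and 404 with DESeq2). Over both sexes they were 0 except for 6 with surrogate variables (2 higher, 4 lower), 2 without the 3 lung-rich libraries and 3 without the 5. These were Clic5 (0.40, adjusted p 0.0393) and Fasn (-0.39, 0.0393) over 17 libraries, and Lrrc4b (-0.47, 0.00925), Plekha7 (-0.34, 0.0210) and Erbb2 (-0.33, 0.0266) over 15, named after their values were seen, with 0.02, -0.69, -0.22, -0.18 and -0.19 over all 20. Leaving out single libraries gave 0 in every diet contrast and 3 to 4 genes for sex.

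Lists called over both sexes fell from 22 to 0 with an estimated correlation and 0 with fry, in males from 17 to 1 and 0, in females from 17 to 0 and 0. Leaving out single libraries gave 14 (without control male 4) to 25 (without obese female 5) over both sexes, 11 (without obese male 3) to 27 (without control male 4) in males and 15 to 21 in females. The agreement of the 2 sexes ran from -0.707 (without control male 4) to 0.556 (without obese male 1). The cause was not tested for any of these beyond the libraries named.

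Adjusted p over fits without single libraries ran from 6.77e-08 to 0.517 (without control male 4) for sarcomere over both sexes, 4.69e-15 to 0.280 (without obese male 1) for cell cycle and 0.00285 to 0.686 (without control male 4) for skeletal muscle in males, 4.24e-07 to 0.984 (without control female 3) for neutrophil in females, and 1.47e-14 to 0.157 (without obese male 1) for the respiratory chain difference between sexes, which was 0.0792 over 15 libraries. Each reversed in at least 1 of these fits, skeletal muscle without obese male 5 at an adjusted p of 0.411. These readings of described lists were not planned.

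Single genes reversed in fits without certain libraries or with surrogate variables. Over both sexes, fits without single libraries gave Trf -1.71 to 0.091, Ahsg -1.64 to 0.42 and Fgg -1.81 to 0.28, each highest without control female 3, and Slc27a6 -3.99 to 0.054, highest without control male 4. In males Mylpf ran from -0.22 to 3.78, Tnnt3 from -0.54 to 2.94 and Myh8 from -0.52 to 3.09, each lowest without obese male 5. In females Slc4a1 ran from -2.50 to 0.18 and S100a9 from -3.29 to 0.15, highest without control female 3. Over 15 libraries Ikzf1 in females was 0.39 and Ahsg over both sexes 0.0048. With surrogate variables Ahsg, Slc4a1 and S100a9 in females were 0.17, 0.44 and 0.30, and the difference between sexes was -0.46 for Ahsg and -0.11 for S100a9. Of 4149 values for named genes 4076 kept their direction and side of the threshold, and of 580 for described lists 484 did. Most named genes were far from the threshold throughout, so keeping its side says little about them. Values that shrank also count as kept, such as Ahsg in females, from -3.00 to -0.0041 without control female 3.

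With the number in the sample titles as a replicate block, limma-voom called 14 lists over both sexes, 8 in males and 11 in females, and 0 genes in each diet contrast (291, 226, 370 and 236 at an unadjusted p under 0.05). Among pairs of libraries from different groups, the 10 with the same number had a median correlation of 0.289, from -0.0648 to 0.762, and the other 140 had 0.0543. The 0.762 belonged to control female 4 and control male 4, which are both lung-rich. Over 17 libraries the medians were 0.184 for 8 pairs with the same number and -0.0217 for the other 100. Over 15 they were 0.154 for 7 pairs and -0.0194 for the other 75. Control male 2 and control male 3, of 1 group, also share a number, at 0.353 over 20 libraries and -0.395 over 17. The correlation within a number, estimated over all genes with limma-voom, was 0.338 over 20 libraries, 0.237 over 17 and 0.213 over 15. Libraries that share a number are thus not fully separate replicates of a diet. Of 100 splits of the title numbers 92 gave an agreement of the sexes as large as -0.245. The other splits ran from -0.369 to 0.765 with a median of 0.244. An agreement above that of chance is thus not shown. The count looks only for high values, so it cannot tell whether -0.245 is unusually low.

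In simulated data, where depth was not varied, 54% of genes changed 1.5-fold and 76% of those changed 2-fold were recovered over 20 libraries, and 98% of those changed 2-fold over 17. These data lacked the joint shifts of other organs' transcripts, so the shares may not hold for the real libraries.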

Other observations

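The splits of the libraries into other diet or sex groups were planned, and the sets without libraries rich in another organ's transcripts were chosen after the data were seen, as were the lists named below. Over both sexes 100 of 100 splits by diet gave as many genes past the threshold as the 0 found with edgeR (569 at an unadjusted p under 0.05, and 0 with DESeq2 and limma-voom), with a highest other count of 0. In males 69 of 69 and in females 72 of 72 gave as many, with highest others of 0, and for the difference between sexes 100 of 100, with a highest other of 1. Any split gives at least 0 genes, so these counts say nothing about chance. For gene lists, 27 of 100 splits gave at least the 22 called over both sexes (highest other 30), 34 of 69 at least the 17 in males (24) and 44 of 72 at least the 17 in females (23). Chance is thus not excluded for the number of lists called in any of these contrasts. For sex, 1 of 100 splits, the real one, gave as many as 3 genes, and the highest other count was 0. That is the smallest share that 100 splits allow, so chance is unlikely there but not excluded. The 3 genes include Xist, which was also used to check the sex labels.

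Without the 3 lung-rich libraries, all 16 endothelial genes were higher in fetuses of obese dams, with a median of 0.18, and 7 passed when adjusted over the list alone. The preset test gave an adjusted p of 3.91e-09 and an estimated correlation an adjusted p of 0.376, and an exact permutation of the list mean gave p = 0.00465, or 0.173 adjusted. Without all 5 libraries the median was 0.13, with 14 of 16 higher and an exact permutation p of 0.0388, or 0.403 adjusted. Cav1, which forms caveolae, was at 0.30 over 17 libraries with an adjusted p of 0.0598 in edgeR, and Fabp4, a fatty acid binding protein, at 0.35 with 0.0714. Over the same 17 libraries all 25 sarcomere genes were higher with a median of 0.14 and an exact permutation p of 0.00998, and all 19 genes of the tricarboxylic acid cycle with a median of 0.11 and an exact permutation p of 0.00760, both 0.173 adjusted. These 17 still hold the liver-rich control female 3 and the thymus-rich control female 5. Over 15 libraries Myh6 moved from 0.23 to 0.19, Myh7 from 0.045 to -0.018 and Myom2 from 0.31 to 0.17. Tpm1 moved from 0.16 to 0.14, while Nebl rose from 0.18 to 0.21.

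Genes of the conduction system were lower in 7 of 9 cases without the 5 libraries, with a median of -0.49, an adjusted p of 0.252 with an estimated correlation and an exact permutation p of 0.0238, or 0.403 adjusted. Hcn4, the pacemaker channel, was at -0.75 with an adjusted p of 0.0686 in edgeR. Over the permutation tests of 52 lists in each contrast and set of libraries, 0 lists had an adjusted p under 0.05. This says little for males over 17 or 15 libraries, where 30 of 52 lists need the smallest possible p of 0.0286, or for females over 15, where 50 need 0.0476. It is also limited within each sex over 20 libraries and for females over 17, where 9 need 0.00794. There were 2 lists at an unadjusted p under 0.05 over both sexes and 20 libraries, 10 over 17 libraries and 6 over 15.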
